A study of Arabidopsis thaliana with 12 samples.

How the data were processed

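Leaf RNA of Arabidopsis thaliana was measured on 12 single-colour Agilent arrays (Cy3), 1 per sample, in 3 groups given by the labels: control (5), feeding (4) and eggs and feeding (3). The deposited scanner output holds intensity values per spot, which per the file headers were background-subtracted and spatially detrended within each array by Agilent Feature Extraction 11.5.1.1 and were not normalised between arrays. The submitters' processing notes name version 10.1 of that software, so headers and notes differ. Each array held 61657 non-control spots for 59017 probes and 30541 loci, with TAIR10 named in the headers as the genome build. The authors' series matrix holds log2 values of the same arrays, as deposited, with a median of 6.59 or 6.6 in each column. Its log2 scale was found by setting each column against the scanner values (r 0.984 to 0.991, each of the 12 columns closest to its own array), while its centring and normalization are not given in the sources used here. All 12 columns shared a maximum of 17.82, with minima from -2.26 to -1.57, a pattern that quantile normalization gives. These values and the quantile normalization used here may therefore be alike in scaling.

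The processed signal was taken to log2 and each array's 75th percentile was subtracted. Control spots and spots with an outlier mark (12 to 137 per array) were left out, which left 67 missing values, filled with the group mean for list tests and principal components. Spots of a probe were averaged, and the probe with the highest mean over the 12 arrays stood for its gene. Among genes called with several probes above background, a probe had the opposite sign in 21 of 1190 genes for feeding and 20 of 1214 for eggs and feeding. Genes well above background on at least 3 arrays were tested (20787 genes), and 9754 loci were not. Names came from a RefSeq table of genes (assembly TAIR10.1), used for names alone, which matched 20488 of the tested genes; coordinates are those in the files (TAIR10), 1-based. No genome sequence was used here. Where a gene was not well above background on any array of a group, a bound is given as "at least N-fold". It sets the brighter group's mean against the dim group's mean of, per array, the higher of the gene's own signal and the lowest signal among probes well above background. No array had a saturated spot, and the 75th percentile ranged from 341.6 to 671.6 between arrays.

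All 12 arrays entered 1 linear model of group means in limma 3.58.1 (lmFit and eBayes, R 4.3.3, data.table version 1.17.8), with 9 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg over the genes tested at a threshold of 0.05. All gene p-values in the text are from limma unless another test is named. A normalised log2 level is relative to the array's 75th percentile, and changes are differences of group means with standard errors from the fit. Of 27 gene lists, all 435 loci were on the array and 416 were tested. Lists were tested with camera (limma, correlation 0.01), adjusted over the 27 lists, and beside it with an estimated correlation and with fry. At a correlation of 0.01, camera called 12, 13 and 4 lists in feeding over control, eggs and feeding over control, and eggs and feeding over feeding. An estimated correlation left 2 (anti-herbivore proteins and glutathione S-transferases), 1 (anti-herbivore proteins) and 0, and fry called 9, 11 and 0. Exact 2-sided permutations of the list medians were added after the list results were seen. In feeding over control (126 splits, smallest possible permutation p of 0.00794) 12 lists had an unadjusted p under 0.05, 11 of them among the 12 that camera called. In eggs and feeding over control (56 splits, smallest possible permutation p of 0.0179) 9 lists did, 8 of them among the 13 called, and between the fed groups none did. After adjustment over the 27 lists no permutation p was under 0.05 in any comparison, but so few splits leave little room for that. In feeding over control the 4 lists at the smallest possible p had an adjusted permutation p of 0.0536. In eggs and feeding over control the 7 such lists had 0.0689. The adjusted result therefore says little about these lists.

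Groups, gene lists, tests and the rule for named genes were fixed before the data were examined. The rule took the 6 largest rises and falls past the threshold whose arrays did not overlap between groups and that were well above background on every array of the higher group, up to 3 members with the lowest adjusted p of each list described, members of lists with 5 or fewer calls, and 15 fixed defence and photosynthesis genes. In eggs and feeding over feeding it took all genes past the threshold, of which there were 0. Slide and scan day were tested as batches. The alternatives were normexp background correction (offset 50), quantile and median scaling, the series matrix values, no filter and a stricter filter on dim genes, the mean of a gene's probes, only the groups compared, array weights, a trended and robust prior, the replicate number, slide or scan day as a block, slide as a random block, an estimated list correlation, and each array left out in turn. Leaving out both feeding arrays of slide 6 was chosen after the data were seen.

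The procedure was tested on simulated data with 50 genes changed at each fold among 20787. For feeding over control it recovered 28% of genes changed 1.5-fold, 54% at 2-fold, 78% at 4-fold and 88% at 16-fold, with 5.3% of calls false. For eggs and feeding over control it recovered 24, 50, 76 and 88%, with 1.7% false, and for eggs and feeding over feeding 28, 48, 74 and 88%, with 6.3% false. A shifted list was recovered in each comparison and 0 lists were called without a shift. The simulated genes were drawn independently, so this 0 cannot show how often lists of correlated genes are called falsely. In the real data the estimated correlation reached 0.755, for photosystems. Splits of the real arrays reached the real count of 12 lists in 38 of 100 for feeding over control. They reached 13 in 17 of 56 for eggs and feeding over control, and 4 in 34 of 35 between the fed groups.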

Results

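Gene expression was measured in rosette leaves of Arabidopsis thaliana ecotype Columbia-0 after larvae of the large white butterfly, Pieris brassicae, had fed on them, with or without earlier egg deposition by the same insect. Leaf tissue close to the egg or feeding site was taken from 3 groups. The control group (5 arrays) was left untreated for the whole 8 days. In the feeding group (4 arrays) larvae fed for 2 days on plants that had never carried eggs. In the eggs and feeding group (3 arrays) a cluster of eggs was laid on a leaf, and 6 days later larvae fed on that leaf for 2 days. Each RNA sample was labelled with 1 dye and hybridised to its own array, with 59017 probes for 30541 loci. Between 61.5 and 65.5% of the non-control spots were well above background on each array, and no spot was saturated. The 75th percentile of the processed signal lay between 341.6 and 671.6 intensity units. Of the 30541 loci, 20787 were well above background on at least 3 of the 12 arrays and were tested. The number of arrays limits the precision of every comparison. The labels do not say that the samples of a group came from separate plants, so the p-values measure the spread between these samples only. Arrays of 1 group correlated across genes at r between 0.923 and 0.98, and no pair of arrays shared more than 0.002% identical values. The first principal component (40% of the variance) separated control from fed arrays, and the second (16.1%) set feeding replicates 2 and 3, which shared a slide, apart from the other arrays.

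The first comparison asked how 2 days of larval feeding changed transcript levels in leaves without eggs. In the 3 jasmonate lists 39 of 57 members rose, and these lists had the highest medians of the 27 tested. With an estimated correlation the anti-herbivore list kept its call (adjusted p = 0.0222), while synthesis, signalling and turnover (adjusted p = 0.228) and the jasmonate and ethylene branch (adjusted p = 0.0931) did not. VSP2, a vegetative storage protein with anti-insect activity (AT5G24770, chromosome 5, 8500713 to 8501844, TAIR10), rose 55.5-fold, from a normalised log2 level of 1.27 ± 0.56 (SD, n = 5) to 7.07 ± 0.52 (SD, n = 4). The plant defensin PDF1.2 (AT5G44420, chromosome 5, 17907216 to 17907550) rose 256-fold, with a log2 change of 8.00 ± 0.83 (SE). The tryptophan and camalexin list (10 of 13 members passed) and the glutathione S-transferase list (7 of 14) rose as well, and the Calvin cycle list fell (5 of 16). With an estimated correlation these lists had an adjusted p = 0.155, 0.0222 and 0.344. In all, 836 genes rose and 799 fell at an adjusted p under 0.05 in limma, and of the 817 that changed at least 2-fold, 602 rose and 215 fell.

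Among 30 measured genes of jasmonate synthesis, signalling and turnover, 18 rose and none fell, or 28 and 1 adjusted over the list alone. The list's median log2 change was 2.45 (camera, adjusted p = 4.09e-20), with an adjusted p = 0.228 with an estimated correlation. LOX2, a chloroplast lipoxygenase of jasmonate synthesis (AT3G45140, chromosome 3, 16525437 to 16529233), rose 3.15-fold (log2 1.65 ± 0.12, SE). The allene oxide cyclases AOC1 and AOC2 rose 4.50-fold and 3.55-fold. JAZ10, a repressor of jasmonate signalling, rose 31.6-fold (log2 4.98 ± 1.07, SE, adjusted p = 0.0211). In control replicate 2 it was at 0.78 against -5.19 to -2.70 in the other controls, which lowers the measured rise. Control replicate 2 stood apart on this list, at a median of 1.74 above the control mean against -0.60 to -0.17 in the other controls, and without it 26 members rose at a median of 3.10. Of 17 jasmonate-responsive anti-herbivore proteins, 14 rose and none fell (15 and 1 adjusted over the list alone), at a median of 3.58 (camera, adjusted p = 2.73e-22). That call held with an estimated correlation (adjusted p = 0.0222). VSP1 rose 76.2-fold and CORI3, a cystine lyase, 5.08-fold.

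In the branch controlled jointly by jasmonate and ethylene, 7 of 10 members rose (10 adjusted over the list alone), at a median of 5.67 (camera, adjusted p = 3.73e-13, and adjusted p = 0.0931 with an estimated correlation). The defensins PDF1.2c, PDF1.2b, PDF1.3 and PDF1.1 had log2 changes of 9.04, 8.34, 8.23 and 7.68. Their sequences are close, so a probe may read more than 1 of them, and PDF1.2c and PDF1.3 were well above background on 2 and 1 of the 5 control arrays. ERF1, a transcription factor of this branch, had a log2 change of 2.5 ± 0.69 (SE) and did not pass (adjusted p = 0.0518). BSMT1, a methyltransferase acting on benzoic and salicylic acid, was outside the lists and among the 6 genes with the largest rise (log2 8.66 ± 0.93, SE, well above background on 1 control array).

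Of 13 genes of tryptophan and camalexin synthesis, 10 rose (12 adjusted over the list alone), at a median of 1.61 (camera, adjusted p = 3.9e-12, and adjusted p = 0.155 with an estimated correlation). CYP79B3, which converts tryptophan to indole-3-acetaldoxime, rose 4.22-fold, TRP1 2.97-fold, TSA1 3.05-fold and PAD3, the last enzyme of camalexin synthesis, 7.21-fold. Of 15 indolic glucosinolate genes 3 rose (5 adjusted over the list alone): CYP81F4, CYP83B1 and GSTF10, by log2 7.64, 1.06 and 1.06. The list median was 0.50 (camera, adjusted p = 0.00443, and adjusted p = 0.25 with an estimated correlation), and 0.274 and 0.303 without control replicate 4 and feeding replicate 3. Of 14 glutathione S-transferases 7 rose (10 adjusted over the list alone), at a median of 1.36, or 1.25 with dim members at their bounds. That call (camera, adjusted p = 4.99e-08) held with an estimated correlation (adjusted p = 0.0222). GSTF2 rose 2.67-fold, GSTF3 2.70-fold, GSTU10 4.98-fold and GSTU4 19.0-fold. The flavonoid and anthocyanin list had 2 of 19 members up (10 adjusted over the list alone), the anthocyanin regulators MYB113 (log2 4.96 ± 0.69, SE) and PAP2 (1.85 ± 0.45, SE). Its median was 1.59 (camera, adjusted p = 5.35e-06, and adjusted p = 0.344 with an estimated correlation), while CHS, chalcone synthase, was at 0.97 ± 0.60 (SE, adjusted p = 0.355). The 4 feeding arrays were uneven on this list, at 2.47, 0.02, 0.86 and 2.52 above the control mean, and over the alternatives the median ranged from 0.578 to 2.495.

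Of 16 Calvin cycle genes, 5 fell (10 adjusted over the list alone): TKL1, RBCS2B, RBCS1B, PRK and SBPASE, with log2 changes of -0.54, -0.75, -0.87, -0.55 and -0.54. All 16 members had a negative change, with a list median of -0.45 (camera, adjusted p = 5.35e-06, and adjusted p = 0.344 with an estimated correlation). RBCS1A, the Rubisco small subunit gene fixed for every comparison, was at -0.01 ± 0.18 (SE, adjusted p = 0.986); small subunit genes are near copies and their probes may read each other. The 38 genes of photosystems and light harvesting had a median of -0.03 (camera, adjusted p = 0.412), and 1 of them fell, the antenna gene LHCB4.3 (-1.75, adjusted p = 0.0315), with 0 adjusted over the list alone. The list passed in 4 of 24 alternatives: in the series matrix values (-0.167, adjusted p = 0.000222), without both slide 6 arrays (-0.271, adjusted p = 0.000341), without feeding replicate 2 (-0.138, adjusted p = 0.0229) and without control replicate 1 (-0.106, adjusted p = 0.0352). Over all 24 the median ranged from -0.271 to 0.052 and the adjusted p from 0.000222 to 0.999.

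The wound and pattern-triggered early genes had 3 of 17 members up, also adjusted over the list alone: the kinase MKK9 (log2 1.26), the NADPH oxidase RBOHD (1.31) and the zinc finger factor ZAT12 (3.01). The list median was 1.2 (camera, adjusted p = 0.00443, and adjusted p = 0.524 with an estimated correlation), and control replicate 2 stood at 2.16 against -0.66 to -0.28 in the other controls. Without that array 7 members rose, and without feeding replicate 2 the list median was 0.674. Among 12 leaf senescence genes PPH and NYE2, both of chlorophyll breakdown, and the asparagine synthetase ASN1 rose (log2 1.44, 1.95 and 2.22), or 5 adjusted over the list alone, at a median of 1.00 (camera, adjusted p = 0.000136, and adjusted p = 0.344 with an estimated correlation). In the ethylene list 1 of 11 rose, the ACC oxidase ACO4 (1.76), also adjusted over the list alone, at a median of 0.38 (camera, adjusted p = 0.0297, and adjusted p = 0.25 with an estimated correlation). With slide as a block the adjusted p of this list was 0.151, and it ranged from 0.00985 to 0.25 over the alternatives. Of 9 heat shock genes HSP17.4 and HSP17.6A rose (log2 2.83 and 2.95), or 4 adjusted over the list alone, at a median of 1.04 (camera, adjusted p = 0.00486, and adjusted p = 0.344 with an estimated correlation). With genes well above background on all 12 arrays the adjusted p was 0.123, and over the alternatives it ranged from 0.00064 to 0.344. The 2 gene calls depended on the settings: without control replicate 2 no member passed, and HSP17.4 and HSP17.6A lost their calls in 12 and 16 of 23 alternatives. HSP17.6A lay low in the controls, at -7.70 to -5.02, and feeding replicate 1 was within that range (-5.65). The size of its rise is therefore uncertain.

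Salicylic acid markers gave few calls. PR1, an antimicrobial marker of salicylic acid signalling (AT2G14610, chromosome 2, 6241944 to 6242429), was at log2 0.32 ± 0.50 (SE, adjusted p = 0.737), PR2 at 1.43 ± 0.49 (adjusted p = 0.1) and PR5 at -0.15 ± 0.64 (adjusted p = 0.909). Of 27 members of the salicylic acid list, EDS5 rose by log2 1.78 and FMO1 at least 1.87-fold (adjusted p = 0.0475, well above background on 1 feeding array), also 2 adjusted over the list alone, and the median was 0.22 (camera, adjusted p = 0.166). Control replicate 2 stood at 0.56 on this list against -0.23 to -0.12 in the other controls, and without it the adjusted p was 0.00786 at a median of 0.28, in a range of 0.00786 to 0.697 over the alternatives. None of 10 egg-responsive markers passed, over all genes or adjusted over the list alone (median 0.72, adjusted p = 0.135), SAG13 among them at 1.02 (adjusted p = 0.282). The list passed as higher in 3 of 24 alternatives, with slide as a block (1.041, adjusted p = 0.0098), without feeding replicate 2 (0.986, adjusted p = 0.0188) and without both slide 6 arrays (1.372, adjusted p = 0.00743), in a range of 0.00743 to 0.524. A rise of these markers with feeding alone therefore stays open. None of 25 aliphatic glucosinolate genes passed in either way (median 0.09, adjusted p = 0.677, passing in 2 of 24 alternatives, in a range of 0.00353 to 0.938), with their regulator MYB28 at -0.81 ± 0.25 (SE, adjusted p = 0.0682). ICS1, the main enzyme of salicylic acid synthesis, was not well above background on 3 arrays and was not tested.

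The 6 largest falls were in AT5G22580 (11.7-fold, log2 -3.54 ± 0.57, SE), the peroxidase AT5G58390 (log2 -3.18), AT5G15780 (-2.83), AT5G22460 (-2.23), AT4G19380, of the fatty alcohol dehydrogenase family, and the kinase WNK3. The last 2 were not well above background on any feeding array and fell at least 7.33-fold and at least 4.44-fold. Apart from feeding replicate 2, AT5G58390 was about as dim as AT4G19380 in feeding. It was at -7.49, -3.64, -6.44 and -6.38 in replicates 1 to 4, so the size of its fall is uncertain.

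**Figure D1:**
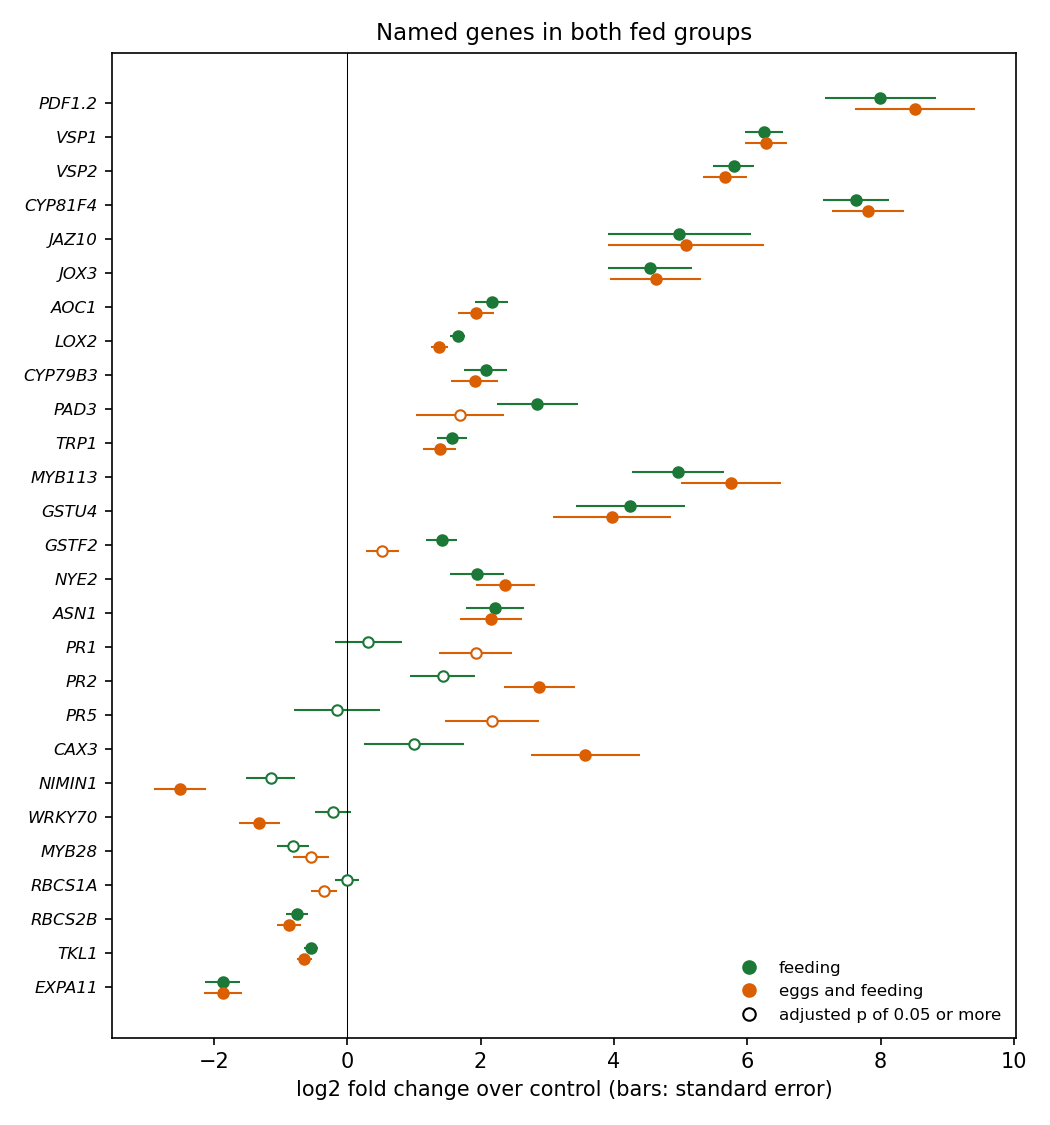
Log2 fold changes of named genes in feeding over control (4 against 5 arrays) and in eggs and feeding over control (3 against 5 arrays), with bars of 1 standard error. The defensin PDF1.2 and VSP2 lie far to the right in both comparisons, while PR2 lies at 1.43 in feeding and 2.88 in eggs and feeding.

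The direction of these calls held within batches, though the genes were chosen on these same arrays, so this is not an independent test. Over the 1635 genes called, the median difference in the direction of the call was 1.00, and it was 1.00 and 1.11 within scan days 1 and 2, 1.3 within slide 1 and 1.03 within slide 4. All 53 named genes that passed kept their direction in these 4 batches, and 11 of the 12 lists called did. The ethylene list was at -0.01 within slide 4. These batches overlap, since slide 1 was scanned on day 2 and slide 4 on day 1. Day 1 held 1 feeding array and day 2 held 1 control array. With scan day as a block 666 genes rose and 601 fell, and with slide as a block, which left 4 residual degrees of freedom, 379 rose and 72 fell. With slide as a block 11 of the 12 lists kept their call, and with scan day as a block all 12 did. The balance of rises and falls depended on scaling: 762 rose and 1118 fell after quantile normalization, and 727 and 1120 after median scaling. Of genes changed at least 2-fold, 538 rose and 311 fell after quantile normalization and 420 and 62 after normexp background correction. Without control replicates 1, 3 or 5 the count of calls was 779, 811 or 1085, and without feeding replicates 1 or 4 it was 719 or 896.

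The second comparison asked how leaves that had carried eggs and were then fed upon differed from untreated leaves. The jasmonate-dependent lists again had the highest medians, and the median of the egg-responsive markers was higher, with 2 of 10 members past the threshold and an adjusted p = 0.0905 with an estimated correlation. VSP2 rose 50.8-fold (log2 5.67 ± 0.33, SE), PDF1.2 366-fold (8.52 ± 0.90, SE) and PDF1.2c by log2 9.88 ± 0.97 (SE). PR2, a beta-1,3-glucanase induced by salicylic acid (AT3G57260, chromosome 3, 21188709 to 21189822), rose 7.35-fold, from 2.89 ± 0.86 (SD, n = 5) to 5.77 ± 0.31 (SD, n = 3), at an adjusted p = 0.0108. The Calvin cycle and photosystem lists had negative medians, with 4 of 16 and 2 of 38 members past the threshold. Neither list passed with an estimated correlation (adjusted p = 0.293 and adjusted p = 0.483), and the photosystem list did not pass after quantile normalization. In all, 797 genes rose and 845 fell at an adjusted p under 0.05 in limma, and of the 888 that changed at least 2-fold, 603 rose and 285 fell.

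Of the 10 egg-responsive markers, PR2 and CAX3, a vacuolar cation exchanger (log2 3.57 ± 0.82, SE, adjusted p = 0.0261), rose, and 9 did adjusted over the list alone. CAX3 was uneven, at 3.02, 2.36 and -0.69 on the 3 eggs and feeding arrays. Its change was 2.84, 3.17 and 4.70 without replicates 1, 2 and 3 of that group, and it did not pass without replicates 1 or 2 (adjusted p = 0.136 and 0.0942), without control replicates 1 or 4 (adjusted p = 0.0599 and 0.0533) or with slide as a block (2.93, adjusted p = 0.166), in a range of 0.00477 to 0.166 over the alternatives. The list median was 1.94 (camera, adjusted p = 2.96e-06, and adjusted p = 0.0905 with an estimated correlation). PR1 was at 1.92 ± 0.55 (SE, adjusted p = 0.0568), PR5 at 2.17 ± 0.70 (adjusted p = 0.0837) and SAG13 at 1.96 ± 0.59 (adjusted p = 0.0687). The egg-responsive list shares KTI1, SAG13 and FRK1 with the anti-herbivore, leaf senescence and wound lists, so its rise is not separate from theirs. PR1, PR2 and PR5 also belong to the salicylic acid list, of whose 27 members 5 rose and 4 fell (7 and 5 adjusted over the list alone), with a median of 0.15 (camera, adjusted p = 0.348). Without control replicate 2, which stood apart on this list, 8 rose and 2 fell. PR2, EDS5, DMR6 and AZI1 rose by log2 2.88, 1.74, 0.99 and 1.96, and FMO1 at least 2.83-fold. NIMIN1, a protein that binds the salicylic acid receptor NPR1, fell (log2 -2.51 ± 0.40, SE), as did the transcription factors WRKY70 (-1.32) and WRKY54 (-1.3) and the immune regulator EDS1 (-0.96).

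In jasmonate synthesis, signalling and turnover 16 of 30 genes rose (24 adjusted over the list alone), at a median of 2.33, or 2.31 with dim members at their bounds (camera, adjusted p = 1.83e-19, and adjusted p = 0.203 with an estimated correlation). LOX2 rose 2.6-fold, AOC1 3.82-fold, JAZ10 33.8-fold and JOX3, a jasmonate oxidase, 24.7-fold. The JAZ10 rise is again lowered by control replicate 2, at 0.78 against -5.19 to -2.70 in the other controls. Without control replicate 2, which stood apart on this list, 26 members rose at a median of 2.82. Of 17 anti-herbivore proteins 13 rose and none fell (15 and 1 adjusted over the list alone), at a median of 3.67 (camera, adjusted p = 1.07e-23), and that call held with an estimated correlation (adjusted p = 0.0247). VSP1 rose 77.8-fold and CORI3 4.47-fold. In the jasmonate and ethylene branch 7 of 10 rose (8 adjusted over the list alone), at a median of 5.75 (camera, adjusted p = 2.69e-13, and adjusted p = 0.0905 with an estimated correlation), with PDF1.3, PDF1.2b and PDF1.1 up by log2 9.29, 8.97 and 8.19. ERF1 was at 2.06 ± 0.75 (SE, adjusted p = 0.123). BSMT1 rose by log2 8.12 ± 1.01 (SE).

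Of 13 tryptophan and camalexin genes 8 rose (11 adjusted over the list alone), at a median of 1.39 (camera, adjusted p = 1.13e-09, and adjusted p = 0.203 with an estimated correlation). CYP79B3 rose 3.77-fold, TRP1 2.61-fold and TSB2 2.39-fold, and PAD3 was at 1.69 ± 0.66 (SE, adjusted p = 0.145). In the indolic glucosinolate list CYP81F4 and CYP83B1 rose (log2 7.81 and 0.88), also 2 adjusted over the list alone, at a median of 0.23 (camera, adjusted p = 0.0155, and adjusted p = 0.293 with an estimated correlation). Without control replicate 3 the median was 0.346. That call was lost without control replicate 4 (0.135, adjusted p = 0.0699) or eggs and feeding replicate 3 (adjusted p = 0.0523), within a range of 0.000644 to 0.293 over the alternatives. In the aliphatic glucosinolate list BCAT4, of methionine chain elongation, rose (0.94, adjusted p = 0.0389), with 0 adjusted over the list alone, and the 25 members had a median of 0.37 (camera, adjusted p = 0.000493, and adjusted p = 0.606 with an estimated correlation), or 0.246 without control replicate 5. MYB28 was at -0.54 ± 0.27 (SE, adjusted p = 0.246). Among 19 flavonoid and anthocyanin genes MYB113 and PAP2 rose (log2 5.76 and 2.02), or 11 adjusted over the list alone, at a median of 1.80 (camera, adjusted p = 4.37e-07, and adjusted p = 0.293 with an estimated correlation). CHS was at 1.14 ± 0.65 (SE, adjusted p = 0.32). Of 14 glutathione S-transferases GSTU10 and GSTU4 rose (2.47 and 3.98), or 3 up and 1 down adjusted over the list alone, at a median of 0.53 (camera, adjusted p = 0.0024, and adjusted p = 0.203 with an estimated correlation). With genes well above background on all 12 arrays the adjusted p was 0.056, in a range of 4.93e-05 to 0.203 over the alternatives.

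Of 16 Calvin cycle genes TKL1, RBCS2B, SBPASE and PRK fell (log2 -0.65, -0.87, -0.72 and -0.63), or 13 adjusted over the list alone, at a median of -0.47 (camera, adjusted p = 9.48e-07, and adjusted p = 0.293 with an estimated correlation). RBCS1A was at -0.35 ± 0.19 (SE, adjusted p = 0.303). All 38 photosystem and light-harvesting genes had a negative change and 2 fell, PSBQ-1 (-0.56) and PSBS, of non-photochemical quenching (-0.65), also 2 adjusted over the list alone. The list median was -0.41 (camera, adjusted p = 6e-08, and adjusted p = 0.483 with an estimated correlation), but -0.08 after quantile normalization (adjusted p = 0.0743, in a range of 3.91e-11 to 0.483 over the alternatives). Of 12 senescence genes PPH, NYE2, ASN1 and PAO rose (log2 1.36, 2.37, 2.16 and 0.81), or 7 adjusted over the list alone, at a median of 1.33 (camera, adjusted p = 3.1e-06, and adjusted p = 0.274 with an estimated correlation), or 0.647 without eggs and feeding replicate 1. Of 17 wound and pattern-triggered genes MKK9, RBOHD and ZAT12 rose (0.93, 1.37 and 3.12), also 3 adjusted over the list alone, at a median of 1.12 (camera, adjusted p = 0.00264, and adjusted p = 0.483 with an estimated correlation). Control replicate 2 stood apart on this list too, and without it 8 members rose. The 6 largest falls were in AT5G22580 (15.5-fold), AT3G59370 (log2 -3.66 ± 0.30, SE), AT1G70880 and AT4G19380 (-3.91 and -3.68, each well above background on 1 of the 3 eggs and feeding arrays), AT1G12080 (at least 11.6-fold) and WNK3 (at least 7.74-fold).

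**Figure D2:**
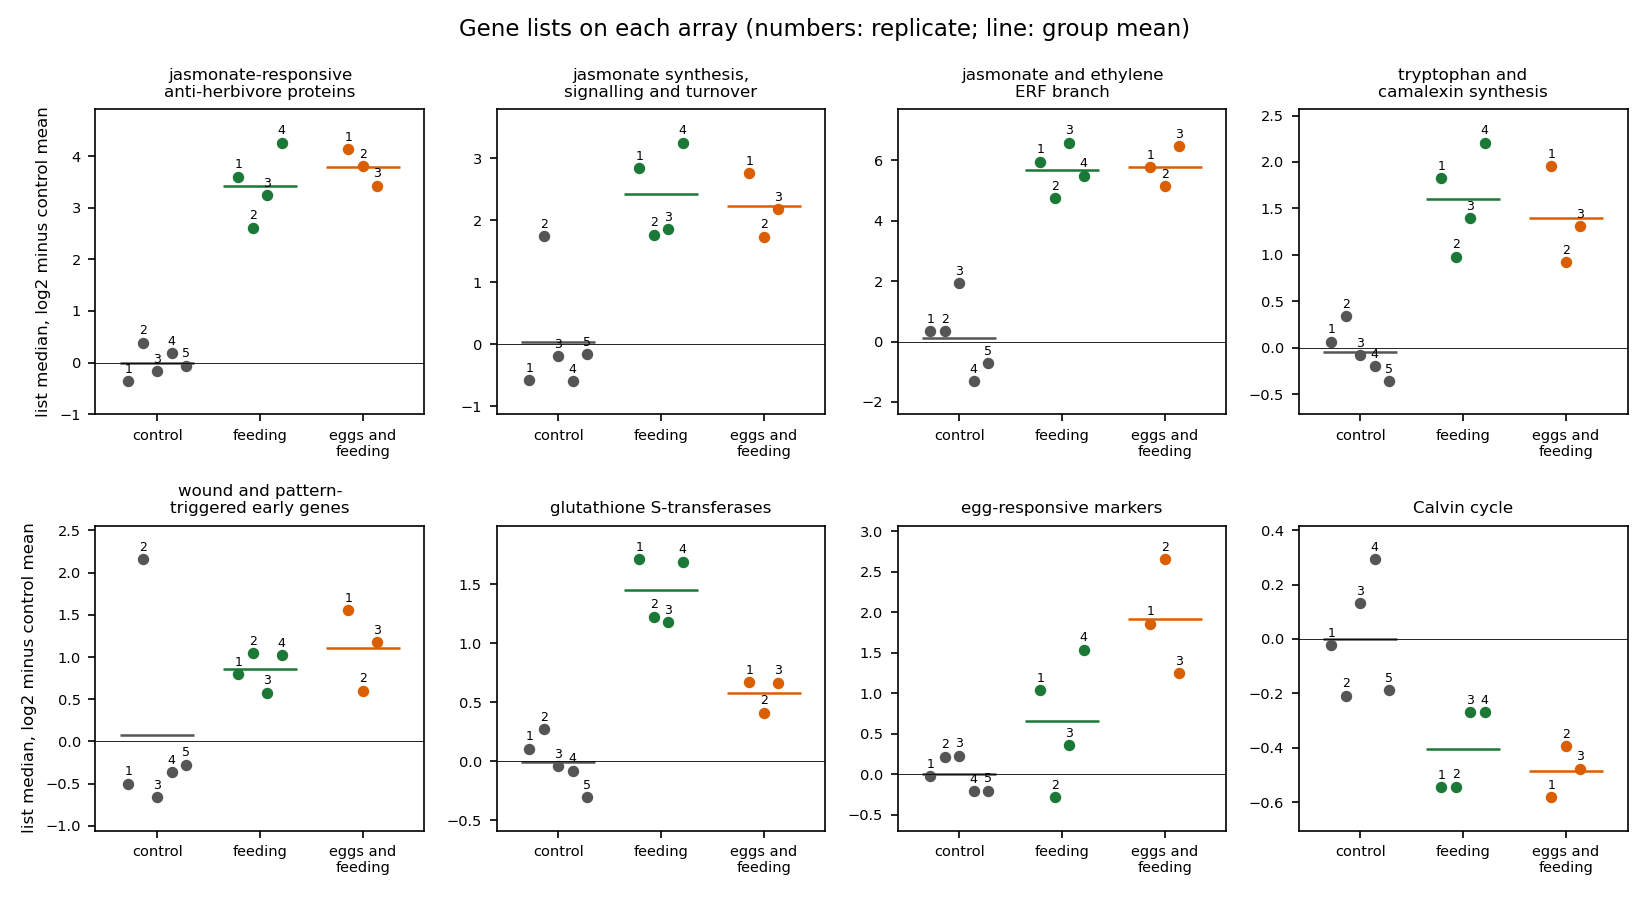
Median log2 level of 8 gene lists on each of the 12 arrays, relative to each gene's mean over the 5 control arrays, with a line at each group's mean. Control replicate 2 lies above the other controls on the jasmonate synthesis list (1.74) and on the wound list (2.16).

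Within scan days 1 and 2 the median difference over the 1642 genes called was 1.04 and 1.17 in the direction of the call, against 1.09 over all arrays, and within slides 4 and 5 it was 1.27 and 0.78. All 53 named genes that passed and all 13 lists called kept their direction in these 4 batches. The calls came from these same arrays, and both slides were scanned on day 1, so this is not an independent test and the batches overlap. With scan day as a block 751 genes rose and 770 fell, and with slide as a block 297 rose and 43 fell; all 13 lists kept their call with either block. Without eggs and feeding replicates 1 or 2 the count of calls was 383 or 725, and without control replicates 1 or 3 it was 882 or 944.

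The responses of both fed groups overlapped. Of the genes called against control, 608 rose in both comparisons, 468 fell in both and 0 moved in opposite directions. Independent lists of these sizes would share 32.1 and 32.5 genes. Both comparisons use the same control arrays. All 3 groups, controls included, were simulated without change and with genes drawn independently. A median of 0 genes was then called in each direction of each comparison. Their shared count of 0 was thus fixed in advance and tests nothing about the overlap. Across genes, which are not independent replicates, the fold changes correlated at r = 0.832 against a simulated 0.408, and their covariance was 0.477 against a simulated 0.059, a difference of 0.419. When the 5 controls were split so that each comparison had its own, the 10 splits gave a median of 228 shared rises (162 to 275) and 44.5 shared falls (17 to 97), where independent lists would share 5.95 and 1.32, with a median r of 0.688 and a median covariance of 0.438. A further 559 genes passed in feeding alone and 566 in eggs and feeding alone, of which 551 and 556 had the same sign in the other comparison. Shared controls alone favour the same sign, and no baseline was taken for these called genes. Over all genes 79.3% had the same sign, against a simulated 63.3% and a median of 70.5% with split controls. None of the genes that passed in 1 comparison alone passed the test between the fed groups, but no gene did, so this count was fixed in advance. Without control replicates 1 or 3 the overlap was 548 or 581 genes, without feeding replicates 1 or 4 it was 544 or 710, and without eggs and feeding replicates 1 or 2 it was 339 or 628.

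**Figure D3:**
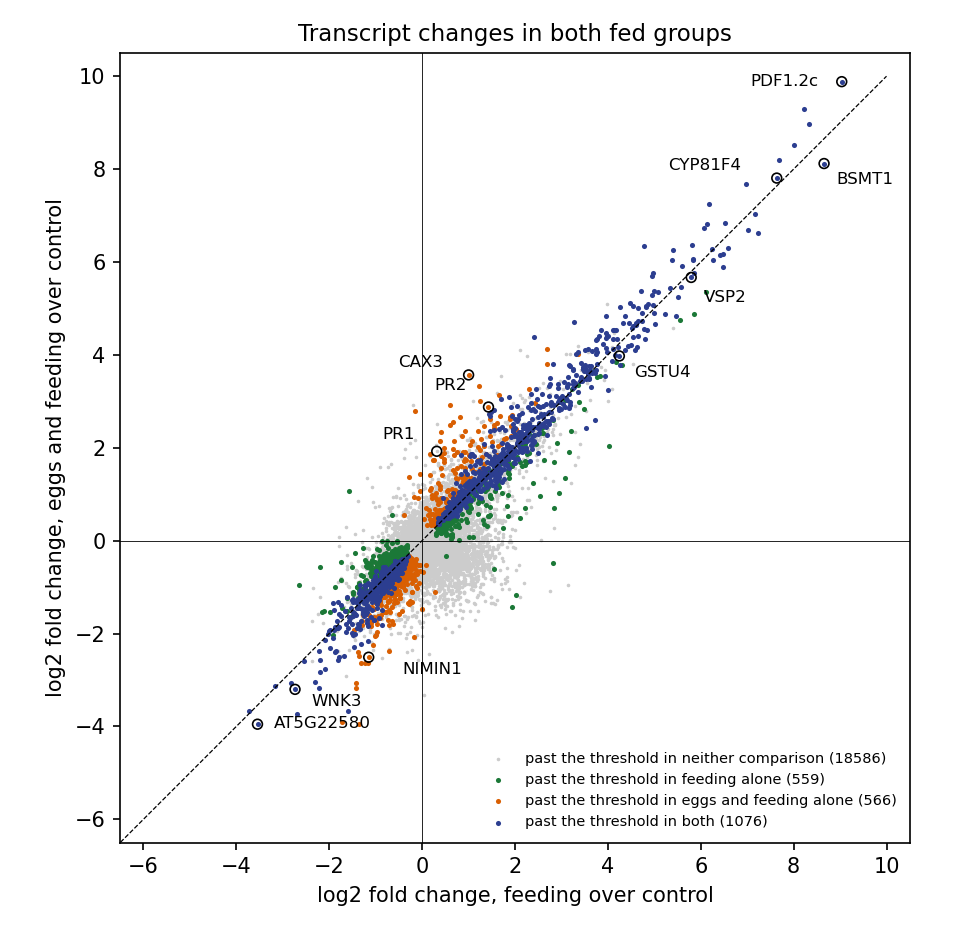
Log2 fold change of each of 20787 genes in eggs and feeding over control (vertical axis) against feeding over control (horizontal axis), coloured by the comparisons in which the gene passed, with the line of equal change dashed. The 1076 genes past the threshold in both lie along that line, and both axes share the 5 control arrays.

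The third comparison asked whether a leaf that was fed upon responded differently when it had carried eggs. No single gene passed. In limma 0 of 20787 genes reached an adjusted p under 0.05, the lowest being 0.391, while 974 had an unadjusted p under 0.05; with quantile normalization 1 gene passed, and without feeding replicate 1 there were 2. Small shared shifts were measured in 4 of the 27 lists with a preset correlation, and no member of them passed over all genes. The medians of egg-responsive markers and aliphatic glucosinolate genes were higher in eggs and feeding than in feeding alone, and those of glutathione S-transferases and photosystem genes were lower. None of the 4 lists passed with an estimated correlation (adjusted p = 0.0579, 0.784, 0.0806 and 0.76). The aliphatic list turned to a median of -0.038 with slide as a block, and photosystems to 0.065 in the authors' series matrix values.

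All 10 egg-responsive markers had a positive difference, with a median of 1.14 (camera, adjusted p = 3.79e-09, and adjusted p = 0.0579 with an estimated correlation). PR5 was at 2.32 ± 0.73 (SE), CAX3 at 2.57 ± 0.85, PR1 at 1.61 ± 0.57 and PR2 at 1.45 ± 0.56, none of them past the threshold (adjusted p = 1). The salicylic acid list of 27 genes, which holds PR1, PR2 and PR5, had a median of -0.168. It did not pass over all arrays or in any of 22 alternatives, at medians of -0.313 to -0.09. For the egg-responsive markers the within-day medians were 0.75 and 1.98 and that within slide 4 was 1.16. With slide as a block their median was 0.478 (adjusted p = 0.0196, in a range of 6.39e-10 to 0.0579 over the alternatives). All 25 aliphatic glucosinolate genes had a positive difference, with a median of 0.30 (camera, adjusted p = 3.77e-08, and adjusted p = 0.784 with an estimated correlation); IPMDH1, MAM3 and MAM1, of methionine chain elongation, were at 1.05, 0.86 and 0.39. This list did not hold within batches: its median was -0.03 and 0.55 within scan days 1 and 2, 0.03 within slide 4 and -0.04 with slide as a block. Of 14 glutathione S-transferases 13 had a negative difference, with a median of -0.66 (camera, adjusted p = 2.38e-05, and adjusted p = 0.0806 with an estimated correlation), and the within-batch medians were -0.84, -0.83 and -0.60. GSTU12 was at -0.78 ± 0.16 (SE, adjusted p = 0.481), GSTF2 at -0.89 and GSTF3 at -0.90, and 3 members passed adjusted over the list alone. Of the 38 photosystem genes 36 had a negative difference, with a median of -0.37 (camera, adjusted p = 1.93e-14, and adjusted p = 0.76 with an estimated correlation), but the median was -0.01 after quantile normalization (adjusted p = 0.767) and 0.065 in the series matrix values (adjusted p = 0.076), in a range of 3.72e-18 to 0.767 over the alternatives. LHCB2.1, PSAD-2 and LHCB3 were at -0.45, -0.43 and -0.45, and the within-batch medians were -0.10, -0.49 and -0.19. With scan day as a block the medians of these 4 lists were 1.01, 0.36, -0.80 and -0.40. Without feeding replicate 2 the egg-responsive and aliphatic lists were at 0.756 and 0.152, and the glutathione S-transferases were at -0.414 without feeding replicate 4 and -0.417 without eggs and feeding replicate 3. No member of the egg-responsive, aliphatic glucosinolate or photosystem list passed adjusted over the list alone.

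The jasmonate lists did not pass in this comparison over all arrays. Their medians were -0.12 for synthesis, signalling and turnover (adjusted p = 0.853), 0.04 for anti-herbivore proteins (adjusted p = 0.256) and 0.43 for the jasmonate and ethylene branch (adjusted p = 0.375). The first depended on the settings: it passed as lower with slide as a block (-0.99, adjusted p = 2.97e-07) and without both slide 6 arrays (-0.668, adjusted p = 0.000115), in a range of 2.97e-07 to 0.998 over the 22 alternatives. The anti-herbivore list passed in 5 of the 22, at medians between -0.311 and 0.271 and adjusted p-values between 0.0112 and 0.953 over all of them. VSP2 differed by -0.13 ± 0.35 (SE), LOX2 by -0.27 ± 0.13, JAZ10 by 0.10 ± 1.22, PDF1.2 by 0.52 ± 0.94 and ERF1 by -0.44 ± 0.79. PAD3 was at -1.16 ± 0.69, CYP79B3 at -0.16, MYB28 at 0.27, CHS at 0.18, RBCS1A at -0.34 and SAG13 at 0.94, with adjusted p = 1 for each of these genes. An exact 2-sided permutation of the 7 fed arrays allows no list a p below 0.0286 and gave 0.143 for egg-responsive markers, 0.257 for aliphatic glucosinolates, and 0.114 each for photosystems and glutathione S-transferases.

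**Figure D4:**
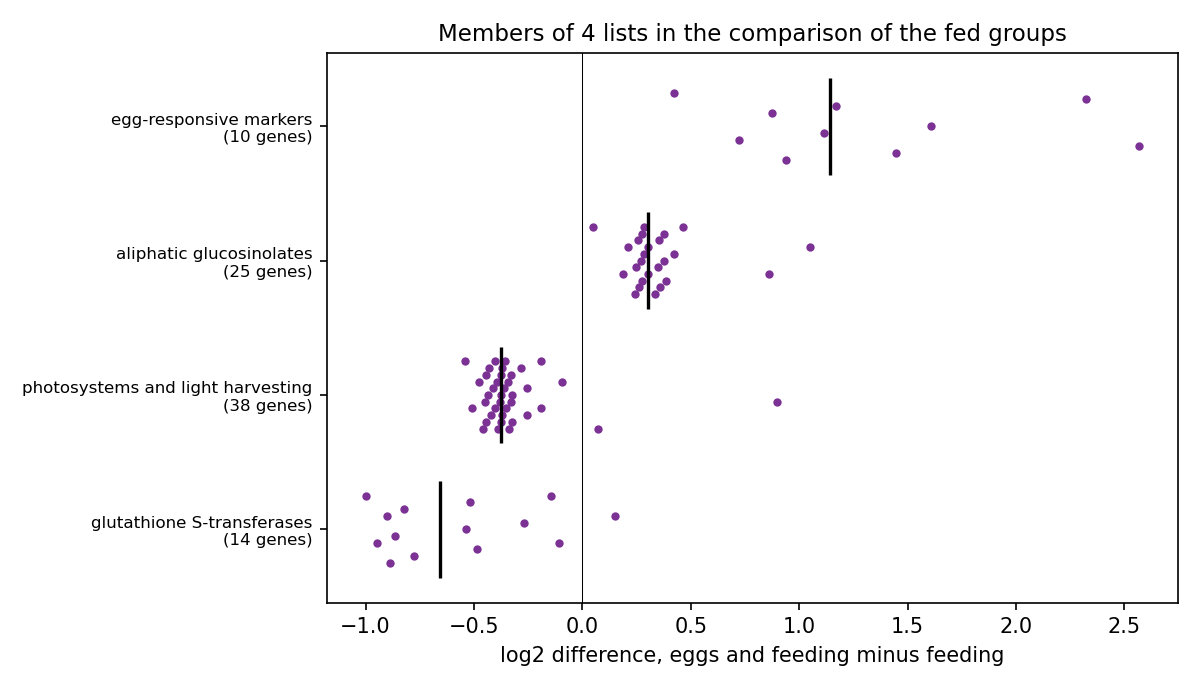
Log2 difference between eggs and feeding (3 arrays) and feeding (4 arrays) for each measured member of the 4 lists called, with the list median as a line. The medians are 1.14, 0.30, -0.37 and -0.66, no single member passed over all genes tested, and the photosystem list turns to 0.065 in the series matrix values.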

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

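The tests chosen only after the result was seen were the counts of splits for 2-fold changes and for gene lists, the exact permutations of the list medians, the closely matched brightness test, the list differences with a spread between arrays and the removal of both slide 6 arrays, which followed the principal components. An array far from the others of its group was found in 7 of 234 tests (3%), where chance finds about 1 in 20. Control replicate 2 was high on 3 lists, with a gap to the next array of 0.817 of the group's range for jasmonate synthesis, signalling and turnover, 0.864 for salicylic acid and 0.864 for wound and pattern-triggered genes. PDF1.3 was high in control replicate 3 (0.827, at -3.89 against -6.33 to -5.91), AT1G70880 was high in control replicate 5 (0.714, at -2.24 against -3.5 to -3.14) and CORI3 was low in control replicate 1 (0.784, at 4.68 against 5.13 to 5.25). In the feeding group MAM1 was low in replicate 2 (0.837, at 3.58 against 4 to 4.08). By the camera test of the difference, 4 lists differed between the fed groups, with medians of 1.144 for egg-responsive markers, 0.303 for aliphatic glucosinolates, -0.373 for photosystems and -0.659 for glutathione S-transferases. None of these kept an adjusted p under 0.05 with an estimated correlation (0.0579, 0.784, 0.76 and 0.0806).

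The lower photosystem list in eggs and feeding could reflect brightness rather than photosynthesis, since 36 of its 38 members were among the 200 brightest genes. Lists drawn from the 20 nearest genes in brightness had a median of -0.424 (95% of them between -0.469 and -0.338), so the list did not stand apart from its neighbours, whereas matching in 50 bins (lower limit -0.268) was too coarse to decide for genes this bright. What these neighbours do was not examined, so the close match cannot separate brightness from a change shared with other bright photosynthesis genes. The photosystem median shrank to -0.098 within scan day 1 and to -0.14 without both feeding arrays of slide 6, as a batch difference would predict. It was -0.493 within scan day 2 and -0.398 with scan day as a block (camera, adjusted p = 4.56e-13). Both slide 6 arrays were scanned on day 2, so these 2 values cannot speak against slide 6. With slide as a block the median stayed negative, at -0.263 (camera, adjusted p = 1.83e-10). Over the alternatives the adjusted p ranged from 3.72e-18 to 0.767. Taken as 1 level per array, the list differed by -0.387 ± 0.206 (SE) with scan day in the model and -0.269 ± 0.193 with slide, each within 2 standard errors of 0, so a batch was not excluded. As large a median came from 4 of the 35 splits of the fed arrays (highest other 0.424), so chance could not be excluded, and an effect of eggs on these genes stays open, as do all these technical explanations.

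The median of the egg-responsive markers stayed higher in eggs and feeding within scan days and without slide 6. The lower within-day median was 0.747, the median without both slide 6 arrays was 0.984, and the lowest with 1 eggs and feeding array left out was 1.044, each against 1.144. Leaving out feeding replicate 2 alone, an array of slide 6, gave 0.756. Day 1 held 1 feeding array and day 2 held 1 eggs and feeding array, so a part played by scan day was not excluded. With slide as a block the median was 0.478 (adjusted p = 0.0196, in a range of 6.39e-10 to 0.0579 over the alternatives), or 0.309 ± 0.442 (SE) as 1 level per array, so a part played by the slides stays open. Chance could not be excluded, since 5 of the 35 splits gave a median as far from 0 (highest other -1.624). As a hypothesis, a lasting response to the eggs may lie behind this shift. It was not tested, since no group had eggs alone.

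For genes called in feeding over control, the real grouping was the only 1 of 100 drawn splits to reach 1635 genes (highest other 702). It was also the only 1 to reach 817 genes changed at least 2-fold (highest other 447). That is the smallest share these splits allow, so chance was unlikely for both counts but not excluded. The split with 702 put control replicates 1, 3, 4 and 5 against the remaining arrays. For eggs and feeding over control 1 of 56 splits, the real one, reached 1642 genes (highest other 2) or 888 genes changed at least 2-fold (highest other 2). This too is the smallest share possible, so chance was unlikely here as well. The counts of lists did not stand out from chance, since 38 of 100 splits reached 12 (highest other 19) and 17 of 56 reached 13 (highest other 21). Between the fed groups the real count was 0 for genes and for genes changed at least 2-fold, which all 35 splits reach by design, so these counts test nothing (highest other 413 and 243). For lists chance was not excluded, since 34 of 35 splits reached 4 (highest other 16). The split with 413 genes set eggs and feeding replicate 1 and feeding replicates 1 and 4 against the rest, which points to a structure of the samples whose cause was not tested. Over the genes called in feeding over control, the lower within-day median was 1.002 against 1 over all arrays, so their difference did not shrink within scan days. These genes were called on the same arrays, and day 1 held 1 feeding array and day 2 held 1 control array. A part played by scan day was therefore not excluded. With 0 genes called between the fed groups there was no within-day difference to take for them.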

How the results depend on the processing

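Leaving out both feeding arrays of slide 6 was the only alternative chosen after the data were seen. Of the lists called, 2 of 12 in feeding over control, 1 of 13 in eggs and feeding over control and 0 of 4 between the fed groups passed in every alternative (24, 23 and 22), and 10, 10 and 2 passed in every one but the estimated correlation. Of 53 named genes called in each comparison with control, 22 and 16 passed in every alternative, and none of these reversed. With an estimated correlation 2, 1 and 0 lists were called, and between the fed groups the medians of 1.144, 0.303, -0.373 and -0.659 stayed while their calls ended, since that setting changes only the p-value. Normexp gave 482 genes changed at least 2-fold in feeding over control and 8 lists between the fed groups. Quantile normalization gave 1 gene between the fed groups, also changed at least 2-fold, and a photosystem median of -0.014, and the series matrix values turned that median to 0.065. Without a filter on dim genes 944 and 952 genes were called against control, with an overlap of 609 and 11 lists between the fed groups. With slide as a block 451 and 340 genes were called, of which 439 and 330 changed at least 2-fold, with an overlap of 281, and 8 lists between the fed groups; fewer residual degrees of freedom (4) come with that block. It turned aliphatic glucosinolates to -0.038 and flavonoids to -0.563 between the fed groups. Slide as a random block gave 1866 and 2256 genes and no list test. Without both slide 6 arrays 1 gene, changed at least 2-fold, and 9 lists were called between the fed groups, with medians of 0.051 for aliphatic glucosinolates, -0.386 for phenylpropanoids and -0.662 for flavonoids. The cause of the other changes was not tested.

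With each array left out in turn, the genes called ranged from 719 (without feeding replicate 1) to 1743 in feeding over control, and those changed at least 2-fold from 497 to 945. In eggs and feeding over control they ranged from 383 (without eggs and feeding replicate 1) to 1814, and from 336 to 1041 for 2-fold changes. The overlap ranged from 339 (without eggs and feeding replicate 1) to 1243. Between the fed groups 0 to 2 genes were called, 0 to 2 changed at least 2-fold, and 5 to 10 lists.

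Replicate numbers did not pair the samples: arrays of the same number correlated in their deviations from the group means at -0.14 to 0.35 (median 0.02, 10 pairs), against -0.45 to 0.32 for different numbers. With the replicate number as a block 1190, 1455 and 0 genes and 12, 15 and 13 lists were called, and the overlap was 829. Of the lists called it ended that of indolic glucosinolates in eggs and feeding over control (adjusted p = 0.191), and 41 and 42 of the 53 named genes kept their call. Signal over background limits the rest: 9754 loci were not well above background on 3 arrays, and for genes dim in 1 group only a bound could be given.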

Other observations

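No test in this part was chosen after its result was seen, apart from leaving out both slide 6 arrays, which is counted among the alternatives. Outside the defence lists, 3 of 8 expansins of cell wall loosening, EXPA11, EXPA6 and EXPA3, fell in feeding over control (log2 -1.87, -1.04 and -0.93), and EXPA11 and EXPA3 did in eggs and feeding over control (-1.86 and -0.99). The other expansins did not pass and went both ways, with EXPA10 at 2.12 and 1.63, and EXPA3 lost its call in 10 of 24 and 8 of 23 alternatives. Their list of 14 expansin and cell cycle genes did not pass (medians -0.30 and -0.20, adjusted p = 0.0803 and 0.243), with 3 lower adjusted over the list alone in each comparison. It passed in 8 of 24 alternatives in feeding over control, among them scan day as a block (-0.573, adjusted p = 0.00962), slide as a block (-0.603, adjusted p = 0.0098) and the removal of control replicate 2 (-0.412, adjusted p = 0.0242), in a range of 0.00962 to 0.524, and in 0 of 23 in eggs and feeding over control. In the epidermis and cuticle list CER3, of wax synthesis, rose (1.22 and 1.38), and the epidermal regulator PDF2 fell (-0.78 and -0.99), as did ATML1 in eggs and feeding over control (-1.01). The list's medians were -0.57 and -0.55 (adjusted p = 0.0853 and 0.144), with 1 member higher and 5 lower adjusted over the list alone in each comparison, and it passed in 3 of 24 and 0 of 23 alternatives. NAC019, a transcription factor of abscisic acid and jasmonate responses, rose in both (3.59 and 3.76), while the abscisic acid list of 21 genes had medians of -0.01 and 0.53 (adjusted p = 0.487 and 0.0752), the first below a mean of 0.43. This list passed in 3 of 24 and 11 of 23 alternatives, with medians of -0.248 to 0.589 and -0.228 to 1.029. In eggs and feeding over control it passed with scan day as a block (0.556, adjusted p = 0.045) and with slide as a block (1.029, adjusted p = 0.000619), in a range of 0.000619 to 0.763. Replicate 1 stood at 1.746 above the control mean there, against -0.022 and -0.203 in the other 2 arrays, so the median rests largely on 1 array. PAL1, of phenylpropanoid synthesis, rose in feeding over control (2.21), and its list of 18 had medians of 0.32 and 0.32 (adjusted p = 0.207 and 0.0766). It passed in 3 of 24 and 8 of 23 alternatives, with medians of 0.013 to 0.764 and 0.14 to 0.651, and with slide as a block in both (0.686 and 0.651, adjusted p = 0.000648 and 0.000352, in ranges of 0.000648 to 0.965 and 0.000336 to 0.672). In eggs and feeding over control ACO4 rose (1.32), with the ethylene list at 0.25 (adjusted p = 0.0926, passing in 4 of 23 alternatives), and the heat shock list at 0.37 (adjusted p = 0.161, passing in 1 of 23) had 0 calls.

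Markers of other leaf cell types gave few calls. Of 6 trichome genes 1 fell in eggs and feeding over control, CPC (-0.84), an inhibitor of trichome formation, with list medians of -0.27 and -0.37 (adjusted p = 0.487 and 0.398). Of 10 vascular genes 1 fell there, the sieve element gene SEOR1 (-0.91), with medians of -0.24 and 0.14 (adjusted p = 0.875 and 0.45, passing in 0 of 24 and 1 of 23 alternatives), the first against a mean of 0.06. The 9 guard cell genes had medians of -0.16 and -0.38 (adjusted p = 0.407 and 0.0766, passing in 0 of 24 and 2 of 23 alternatives). Sulfate assimilation stood at 0.21 and 0.30 (adjusted p = 0.412 and 0.0766, passing in 2 of 24 and 7 of 23 alternatives, with medians of -0.069 to 0.41 and 0.039 to 0.567), protein folding in the endoplasmic reticulum at -0.03 and -0.21 (adjusted p = 0.774 and 0.45) and the circadian clock at -0.32 and 0.15 (adjusted p = 0.425 and 0.653), with 0 calls in these 4 lists by limma; adjusted over the list alone, 2 guard cell genes were lower in eggs and feeding over control. The 15 reference genes stood at -0.03 and -0.04 (adjusted p = 0.774 and 0.86), and at -0.03 between the fed groups, where quantile and median scaling and the series matrix values gave 0.004, 0.033 and 0.045.

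Eggs may amplify the response to feeding as a whole, which would make genes changed by feeding change further in plants that had eggs. Over 3247 genes called in all fed arrays against control (1438 higher and 1809 lower), the median difference between the fed groups in the direction of the change was 0.041. As high a value came from 13 of the 35 splits of the fed arrays, with the highest other at 0.253, so the hypothesis was not borne out by this test.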
